A study of Oryza sativa with 36 samples.

How the data were processed

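Gene expression was measured by RNA sequencing in whole rice florets of the cultivar IR64 and of a transgenic OsEPF1 overexpression line, OsEPF1-oeS, in 36 libraries that form 12 groups of 3 (2 lines by 6 stages). Per the labels' protocols, plants grew in cabinets at 30 °C by day and 24 °C by night with 12 h of light, developing florets were collected about 75 to 85 days after sowing and mature florets at about 95 days, and each developing replicate mixed RNA of 3 plants, while the pooling of the mature replicates is not given in the sources used here. RNA was extracted with a plant RNA kit and treated with DNase, and poly(A) libraries were built with an NEBNext Ultra kit, per the labels. Replicates are separate samples in the labels. The p-values measure the spread between these samples pooled for each gene over the 12 groups, so each comparison is judged in part by groups outside it.

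The table deposited by the authors holds whole-number read counts per gene, not normalized, for 37862 gene IDs. Per the submitters' processing notes, the tools used were Trimmomatic 0.38, HISAT2 2.1.0, Subread 2.0.0 and featureCounts, with the IRGSP-1.0 genome build. The roles, the treatment of reads that map to several places and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and values of near-identical copies such as the Rubisco small subunit and beta-expansin families are uncertain. All per-sample columns were used.

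The IDs are not paired with names in the count table, and the RefSeq table given matched 1 of the 37862 IDs. Gene names in the text therefore come from 16 lists of 250 ID and symbol pairs, written from general knowledge of rice genes before the data were examined, as were the groups, the tests, the processing alternatives and the rule for naming genes. Of the 250 entries, 142 had a symbol in the RefSeq table and 140 of these lay at the same relative rank along the chromosome within 0.02. The other 2 were dropped, leaving 248 entries. The symbols of the remaining entries, among them OsEPF1, OsEPF2, OsMUTE, OsFAMA, most photosynthesis genes, PKS1, PKS2 and DPW, could not be checked in this way, so their values belong to the IDs printed with them.

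Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 12 groups, libraries were scaled by TMM, and a group-means model without covariates was fitted to all 36 libraries with the robust quasi-likelihood method (glmQLFit, glmQLFTest), which leaves 24 residual degrees of freedom. The 13 comparisons were OsEPF1-oeS minus IR64 at each of 6 stages, their mean, the genotype by stage interaction, and 5 steps between successive stages of IR64. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Log2 fold changes are given ± their standard error, and levels as CPM (counts relative to the TMM-scaled library size) ± SD. Where a group summed to 0 counts over its 3 libraries, the fold is a bound against 3 counts summed over the group. With 1 to 3 counts it is a ratio with a 95% exact interval. Intervals and floors cover counting error only.

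The lists cover stomatal development, guard cell function, photosynthesis, floral organ identity, meristem, meiosis, tapetum and pollen wall, late pollen, cell cycle and DNA replication, secondary wall and lignin, cuticle, wax and silica, abscisic acid and dehydration, heat shock, circadian clock, gibberellin and brassinosteroid, and sugar transport and invertase. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation preset at 0.01) if they had at least 5 tested members, with adjustment over lists and comparisons within the genotype and the development family. A bare p beside a list is this camera adjusted p. With the correlation estimated per list, 0 of the 20 genotype calls and 10 of the 35 development calls held. Counts of list members are over all tested genes unless given as adjusted over the list alone. Meristem, meiosis, tapetum, late pollen, photosynthesis, clock and heat shock lists stand for other cell types, staging, harvest time and handling of the florets.

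The text names OsEPF1, members of the lists, and by ID at most 2 genes per direction and comparison with the largest changes. These were called genes with a mean of at least 1 CPM over the 36 libraries and 1 sign in all 6 stages for the mean. Single stages required a mean of at least 2 CPM and steps of at least 20 CPM over the 6 libraries compared, and both required 3 and 3 libraries that did not overlap. The position of each library on the IR64 course was its projection between adjacent IR64 stage means over the genes called in that step, with an IR64 library's own values left out of its stage mean, compared by exact permutation tests.

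Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter on low counts, at least 5 CPM in at least 3 libraries, a block for the replicate number, fits on the 6 libraries of a comparison, developing stages alone, a prior count of 0.5, and leaving out each library in turn. In the control line the replicate numbers, which the labels give without saying what they share, paired the libraries of stages 3 and 4 (correlation of deviations from group means 0.258 to 0.341) and of stages 4 and 5 (0.196 to 0.453), where each pair was above 0.1. No replicate pair agreed within sampling noise, the lowest chi-square per degree of freedom being 6.45 over genes with at least 50 counts, and the 10 most abundant genes took 2.58% to 5.52% of a library. Tested on simulated data with 200 changed genes, the fit recovered 64% of 2-fold and 95% of 4-fold changes in the genotype comparison of stage 3 (26467 genes, 5 of 164 calls on unchanged genes), 96% and 98% in the mean (26512 genes, 5 of 199) and 65% and 94% in the step from stage 3 to stage 4 (26462 genes, 4 of 163). The simulated changed genes had a mean of at least 2 CPM. All simulated counts had only the spread that follows from a gene's level, without gene-specific spread or libraries that stood apart. The shares recovered may therefore be higher than in the real data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.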

Results

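RNA sequencing counts were compared between florets of the rice cultivar IR64 and florets of OsEPF1-oeS, a transgenic line in the same cultivar that overexpresses OsEPF1, which encodes a secreted peptide that restrains stomatal development. Florets were sampled at 5 developing stages, numbered 1 to 5, from about 75 to 85 days after sowing, and as mature florets at about 95 days, after heading and before anthesis. Each of the 12 groups held 3 libraries, and the 36 libraries had total counts of 22372257 to 55476576. Of 37862 gene IDs, 26726 were tested. The first principal component of log2 CPM held 64.6% of the variance and the second 19.8%. Within groups, the Pearson correlation between replicates across genes, which are not independent, was 0.963 to 0.991. The median SD between replicates was 0.13 to 0.25 on the log2 scale in the developing groups. In mature florets it was 0.30 for IR64 and 0.22 for OsEPF1-oeS. The genotype comparisons ask which genes differed between the lines at each stage, and the steps between stages describe the course of floret development in IR64.

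OsEPF1 (Os04g0637300) was higher in all 18 OsEPF1-oeS libraries, at 1001 to 3773 CPM, than in any of the 18 IR64 libraries, which lay between 0 and 2.50 CPM. The log2 fold change was 9.15 ± 0.27 (SE, n = 3 per line; edgeR adjusted p = 7.7e-20) at stage 1, 9.65 ± 0.27 at stage 2, 10.75 ± 0.29 at stage 3, 12.20 ± 0.31 at stage 4 and 12.69 ± 0.32 at stage 5. In IR64 the counts summed over 3 libraries went from 201 at stage 1 to 39 at stage 5 and 2 in mature florets, while OsEPF1-oeS held 105194 to 246320. The mature ratio was 84870-fold with a 95% exact counting interval of 23490 to 700800. Both counts of mature IR64 came from replicate 3, and without it OsEPF1 was at least 36420-fold higher. The count includes reads of the transgene only as far as they fall on the annotated gene.

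**Figure D1:**
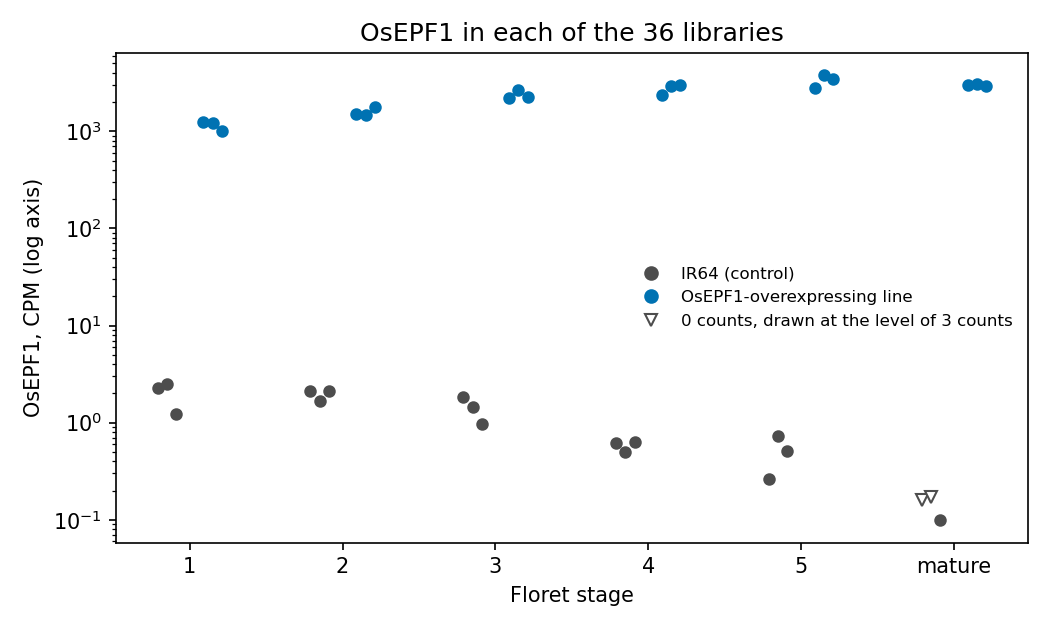
CPM of OsEPF1 in each library on a log axis, by stage and line, with triangles for libraries at 0 drawn at the level of 3 counts. The 18 OsEPF1-oeS libraries sit between 1001 and 3773 CPM, all above the IR64 libraries, of which the highest was 2.50 CPM.

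The stomatal development list held 24 tested genes, and 3 members besides OsEPF1 carried its genotype calls at the developing stages. OsEPF2 (Os04g0457700), which encodes a related signalling peptide, stood at 4.88 ± 0.480 CPM (SD, n = 3) in IR64 and 0.716 CPM in OsEPF1-oeS at stage 1. Its log2 change was -2.76 ± 0.37 (adjusted p = 1.3e-04) at stage 1, -3.52 ± 0.39 at stage 2, -4.83 ± 0.46 at stage 3 and -4.33 ± 0.50 at stage 4. At stage 5 it had 0 counts against 89 and was at least 28.3-fold lower (adjusted p = 8.2e-06), and in mature florets it was at 0 in both lines, so that no mean over the stages could be estimated. OsMUTE (Os05g0597000), the transcription factor that commits cells to the guard mother cell fate, had 2 counts against 146 at stage 1, 68.2-fold lower with a 95% exact interval of 18.6 to 569. It was lower, at -5.18 ± 0.70 (adjusted p = 1.1e-04) at stage 2 and -5.12 ± 0.68 at stage 3, and at least 8.10-fold lower at stage 4 (adjusted p = 0.0069). OsFAMA (Os05g0586300), the factor for guard cell maturation, stood at 0.216 CPM at stage 1 and 2.05 ± 0.337 CPM at stage 5 in IR64, against group means of 0 to 0.0769 CPM in OsEPF1-oeS over the developing stages. It had 1 count against 72 at stage 2 (62.8-fold lower, interval 10.9 to 2514, adjusted p = 0.0034), 0 against 136 at stage 3 (at least 31.2-fold lower) and 2 against 158 at stage 5 (75.5-fold lower, interval 20.5 to 628). At stage 4 the change was -4.44 ± 0.78. Without OsEPF1-oeS replicate 1, which held all 6 counts of that group, OsFAMA was at least 30.3-fold lower. At stage 1 it had 1 count against 20 and in mature florets 5 against 26, neither called.

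**Figure D2:**
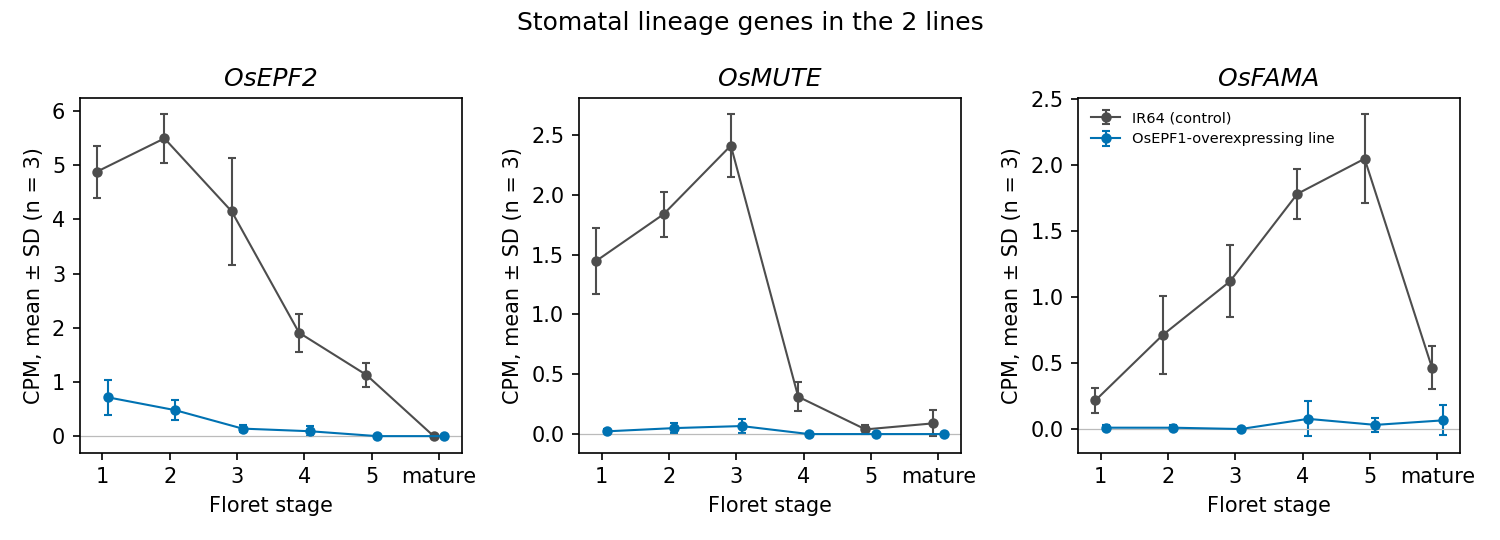
Mean CPM of OsEPF2, OsMUTE and OsFAMA by stage in both lines (points, mean; bars, SD; n = 3 per group). At stage 3, OsMUTE stood at 2.41 ± 0.263 CPM in IR64 and 0.0670 CPM in OsEPF1-oeS.

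In the same list, OsSPCH1 and OsTMM were not called between the lines at any of the 6 stages. OsSPCH1 (Os06g0526100), which starts the stomatal lineage, differed by -1.24 ± 0.45 at stage 1 (adjusted p = 0.34) and 2.38 ± 0.79 at stage 4 (adjusted p = 0.12). The receptor gene OsTMM (Os01g0623000) differed by -0.59 ± 0.24 at stage 1 (adjusted p = 0.48). The list without OsEPF1, an alternative of 23 genes chosen after seeing the data, ranked low in the genotype contrast of stage 1 (camera adjusted p = 0.00103; adjusted p = 0.304 with an estimated correlation) and of the mean over 6 stages (0.0463; adjusted p = 0.607 with an estimated correlation). It was not called at stages 2 to 5 (camera adjusted p 0.139, 0.0729, 0.155 and 0.448) or in mature florets (0.0745). At stages 2 to 5 its median was slightly above 0 (0.03, 0.02, 0.02 and 0.02), while its mean was below 0 (-0.78, -0.91, -0.62 and -0.64). With OsEPF1 the list was not called at stage 1 (camera adjusted p = 0.135) or in the mean (0.424). At stage 1, 1 member was higher and 2 were lower, or 1 and 6 adjusted over the list alone.

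At stage 1, 223 genes differed between the lines, 129 higher and 94 lower in OsEPF1-oeS, of which 88 and 59 by at least 2-fold. In all genotype comparisons, values ± SE are log2 fold changes of OsEPF1-oeS over IR64 with 3 libraries per line. Besides the stomatal genes, PHOT1a (Os12g0101800), a blue-light receptor of the guard cell function list, was higher by 3.32 ± 0.68 (adjusted p = 0.0099). Of the 31 tested photosynthesis genes edgeR called 0 over all genes, with 15 at an unadjusted p under 0.05 and 2 called by DESeq2, while 1 was higher and 13 lower when adjusted over the list alone. The list as a whole ranked low (median -0.57, camera adjusted p = 4.1e-14; adjusted p = 0.323 with an estimated correlation). Of the tapetum, meiosis, meristem, late pollen, clock and heat shock lists edgeR called 0 genes, with 2, 0, 2, 0, 0 and 0 at an unadjusted p under 0.05, and DESeq2 called 1 meristem gene. The lines lay -0.06 apart on the IR64 developmental course. By ID, the genes named were Os03g0629800, with 7683 counts against 0 (at least 2740-fold higher), and Os03g0105500 (814 against 0, at least 290.3-fold higher). On the lower side were Os11g0306400 (0 against 793, at least 247-fold lower) and Os07g0589200 (-3.33 ± 0.37). The count fell to 144 in a fit on the 6 libraries alone, with 110 shared genes, and was 381 with DESeq2. It was 119 without IR64 replicate 1, 147 without replicate 2, 148 without replicate 3 and 138 without OsEPF1-oeS replicate 2. PHOT1a lost its call without IR64 replicate 1 (adjusted p = 0.093), IR64 replicate 3 (0.067) or OsEPF1-oeS replicate 1 (0.072).

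At stage 2, 315 genes differed, 123 higher and 192 lower. EAT1 (Os04g0599300), a transcription factor of the tapetum, was lower, at -4.41 ± 0.58 (adjusted p = 2.5e-05), with 33 counts against 694. UDT1 (Os07g0549600), an earlier factor of tapetum differentiation, was lower, at -0.97 ± 0.22 (adjusted p = 0.016). Among sugar genes, the sucrose transporter gene SUT1 (Os03g0170900) was higher by 1.28 ± 0.29 (adjusted p = 0.017). The cell wall invertase gene CIN2 (Os04g0413500) was lower, at -0.73 ± 0.14 (adjusted p = 0.0032). The photosynthesis list ranked low (median -0.69, 2.3e-15; adjusted p = 0.323 with an estimated correlation), with 0 members called over all genes (edgeR; 25 at an unadjusted p under 0.05, 3 called by DESeq2) and 1 higher and 22 lower adjusted over the list alone. The tapetum list of 19 genes ranked low (median -0.39, or -0.45 with genes at 0 set to their bound; 0.00125; adjusted p = 0.323 with an estimated correlation), with 2 lower, 3 adjusted over the list alone. The secondary wall list of 15 genes ranked low as well (0.0275; adjusted p = 0.692 with an estimated correlation), with 0 called (edgeR; 3 at an unadjusted p under 0.05, 2 called by DESeq2). Of the meristem, meiosis, late pollen, clock and heat shock lists edgeR and DESeq2 called 0 genes, with 1, 2, 0, 0 and 1 at an unadjusted p under 0.05. The OsEPF1-oeS libraries lay -0.22 from IR64 on the developmental course. By ID, the genes named were Os03g0105500 (890 against 0, at least 340.1-fold higher), Os03g0629800 (10.26 ± 0.43) and Os11g0306400 (2 against 1727, 753-fold lower, interval 208 to 6224). The count was 540 with DESeq2, 182 without IR64 replicate 1, 159 without OsEPF1-oeS replicate 2 and 200 without OsEPF1-oeS replicate 3. UDT1 lost its call without IR64 replicate 1 (adjusted p = 0.26), OsEPF1-oeS replicate 2 (0.17) or OsEPF1-oeS replicate 3 (0.083). SUT1 lost its call without IR64 replicate 2 (0.13), IR64 replicate 3 (0.082), OsEPF1-oeS replicate 1 (0.086) or OsEPF1-oeS replicate 2 (0.063). Both were lost in the fit on 6 libraries, as was EAT1, which moved to -6.64 without OsEPF1-oeS replicate 1.

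At stage 3, 453 genes differed, 177 higher and 276 lower. Lsi6 (Os06g0228200), a silicon transporter gene of the cuticle, wax and silica list, was lower, at -2.56 ± 0.26 (adjusted p = 4.2e-07) and CIN2 at -0.98 ± 0.14 (adjusted p = 8.1e-05). Of the 11 meiosis genes, 3 were lower: ZEP1 (Os04g0452500), a central element of the synaptonemal complex, at -1.16 ± 0.25, PAIR2 (Os09g0506800) at -0.92 ± 0.20 and PAIR3 (Os10g0405500), both of the meiotic chromosome axis, at -0.75 ± 0.18. The meiosis list ranked low (median -0.44, 0.0131; adjusted p = 0.423 with an estimated correlation), with 2 members higher and 6 lower adjusted over the list alone. TDR (Os02g0120500), a regulator of tapetum degeneration, was lower, at -1.10 ± 0.24. The tapetum list ranked low (median -0.64, or -0.77 at the bound; 0.00264; adjusted p = 0.329 with an estimated correlation). Among photosynthesis genes PSBS1 (Os01g0869800), of photoprotective quenching, was lower, at -1.30 ± 0.23 (adjusted p = 0.0015) and PSBQ (Os07g0544800), of the oxygen-evolving complex, at -0.86 ± 0.23. Adjusted over the list alone, 1 member was higher and 22 lower (median -0.61; camera 7.6e-16; adjusted p = 0.323 with an estimated correlation). SWEET11 (Os08g0535200), a sugar exporter gene, was lower, at -0.65 ± 0.14. The cuticle list ranked low (0.0115; adjusted p = 0.109 with an estimated correlation), with 1 lower, 2 adjusted over the list alone. Of the meristem, late pollen, clock and heat shock lists edgeR and DESeq2 called 0 genes, with 1, 1, 0 and 3 at an unadjusted p under 0.05. OsEPF1-oeS lay -0.18 from IR64 on the developmental course. By ID, Os03g0105500 (454 against 0) was at least 220.1-fold and Os06g0265100 (409 against 0) at least 198-fold higher. Os11g0306400 (1 against 2559) was 1760-fold lower, interval 316 to 69530. The count was 56 in the fit on 6 libraries (55 shared) and 704 with DESeq2. It was 300 without IR64 replicate 1, 213 without OsEPF1-oeS replicate 2 and 266 without OsEPF1-oeS replicate 3. The 6-library fit lost the call of PSBS1. It also lost those of PSBQ, PAIR2, PAIR3, ZEP1, TDR and SWEET11, which depended on single libraries too. Of these 6 calls, 4 were lost without IR64 replicate 1 (adjusted p 0.064 to 0.33), 2 without IR64 replicate 2 (0.089 to 0.15) and 2 without IR64 replicate 3 (0.052 to 0.084). All 6 were lost without OsEPF1-oeS replicate 2 (0.05 to 0.23) and without OsEPF1-oeS replicate 3 (0.082 to 0.31). PSBQ, TDR and SWEET11 were also lost without both IR64 replicate 1 and OsEPF1-oeS stage 5 replicate 1, which stood apart from their groups.

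At stage 4, 635 genes differed, 290 higher and 345 lower. Lsi6 was lower, at -3.29 ± 0.28 (adjusted p = 1.0e-08) and CIN2 at -0.68 ± 0.14 (adjusted p = 0.0041). Of the 31 photosynthesis genes, 5 were lower, or 20 adjusted over the list alone: RBCS4 (Os12g0292400), of the Rubisco small subunit family, whose near-identical copies make it uncertain how reads were shared, at -1.55 ± 0.35, and SBP (Os04g0234600), of the Calvin cycle, at -1.92 ± 0.44. PSBS1 was lower, at -0.85 ± 0.22, PSAD (Os08g0560900) at -0.64 ± 0.16 and PSAF (Os03g0778100), both of photosystem I, at -0.76 ± 0.20 (list median -0.64, camera 2.4e-13; adjusted p = 0.323 with an estimated correlation). Of the meiosis genes, PAIR1 (Os03g0106300), required for meiotic pairing, was higher by 1.14 ± 0.29 and the cohesin gene REC8 (Os05g0580500) by 0.46 ± 0.12. The list was not called (0.165). In the tapetum list, TDR was lower, at -0.93 ± 0.24, RAFTIN1 (Os08g0496800), of pollen exine formation, at -1.92 ± 0.49 and PKS2 (Os07g0411300), of sporopollenin synthesis, at -2.47 ± 0.51. The list was not called (0.111). Of the meristem, late pollen, clock and heat shock lists edgeR and DESeq2 called 0 genes, with 1, 0, 2 and 0 at an unadjusted p under 0.05. The line lay -0.14 from IR64 on the developmental course. GL1-1 (Os09g0426800), of wax synthesis, was lower, at -1.05 ± 0.25 and SWEET11 at -0.61 ± 0.14. GA3ox1 (Os05g0178100), of gibberellin synthesis, had 27 counts against 1 (31.1-fold higher, interval 5.13 to 1274). By ID, Os03g0115800 (4467 against 2) was 2573-fold higher, interval 712 to 21250. Os11g0306400 was lower, at -7.60 ± 0.72. The count was 396 in the fit on 6 libraries (284 shared) and 1088 with DESeq2. It was 286 without IR64 replicate 1, 328 without IR64 replicate 2, 317 without OsEPF1-oeS replicate 2 and 291 without OsEPF1-oeS replicate 3. Of the 13 named calls apart from Lsi6, CIN2, the stomatal genes and the IDs, 12 were lost without IR64 replicate 1 (adjusted p 0.069 to 0.34), 8 without IR64 replicate 2 (0.062 to 0.21), and 4 without IR64 replicate 3 (0.057 to 0.093). Another 2 were lost without OsEPF1-oeS replicate 1 (0.056 to 0.081), 13 without OsEPF1-oeS replicate 2 (0.052 to 0.21) and 12 without OsEPF1-oeS replicate 3 (0.068 to 0.24). The 6-library fit lost RBCS4, PSBS1, SBP, PAIR1, REC8, TDR, PKS2 and GL1-1. DESeq2 did not call PKS2, and REC8 was not called with upper-quartile scaling or without a filter on low counts.

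At stage 5, 654 genes differed, 303 higher and 351 lower. Of the 19 tapetum and pollen wall genes, 5 were lower: CYP704B2 (Os03g0168600) at -2.61 ± 0.42 (adjusted p = 4.5e-04), CYP703A3 (Os08g0131100) at -2.50 ± 0.45, both fatty acid hydroxylase genes, and DPW (Os03g0167600), a fatty acyl reductase gene, at -3.82 ± 0.80. The others were the polyketide synthase genes PKS1 (Os10g0484800) at -2.81 ± 0.75 and PKS2 at -1.86 ± 0.47. The list ranked low (median -1.41, camera adjusted p = 1.2e-08; adjusted p = 0.109 with an estimated correlation), with 1 higher and 11 lower adjusted over the list alone. HSP17.9A (Os03g0267000), the only called gene of the heat shock list, was lower, at -3.41 ± 0.40 (adjusted p = 3.8e-06), and Lsi6 at -2.04 ± 0.23 (adjusted p = 3.1e-06). The guard cell anion channel gene OsSLAC1 (Os04g0574700) was lower, at -3.41 ± 0.77 and ABA8OX2 (Os08g0472800), of abscisic acid breakdown, at -0.81 ± 0.20. In the meiosis list PAIR2 was higher by 0.91 ± 0.20 and ZEP1 by 0.94 ± 0.25, the opposite sign of stage 3 (interaction adjusted p = 0.0032 and 0.016). The list ranked high (median 0.33, 0.00337; adjusted p = 0.323 with an estimated correlation; 4 higher adjusted over the list alone). In the photosynthesis list RBCS4 was lower, at -1.53 ± 0.28, PSBS1 at -1.18 ± 0.21 and PRK (Os02g0698000), of the Calvin cycle, at -1.08 ± 0.25. The list ranked low (11 lower adjusted over the list alone; median -0.46, 5.8e-11; adjusted p = 0.421 with an estimated correlation). The secondary wall list ranked low (median -0.52, 0.00228; adjusted p = 0.465 with an estimated correlation) and the cell cycle list of 17 genes ranked high (median 0.18, 0.0253; adjusted p = 0.692 with an estimated correlation). Each had 0 called by edgeR and DESeq2, with 6 and 5 at an unadjusted p under 0.05. Of the meristem, late pollen and clock lists edgeR called 0, with 2, 0 and 0 at an unadjusted p under 0.05, and DESeq2 called 1 meristem gene. OsEPF1-oeS lay -0.26 from IR64 on the developmental course. By ID, Os03g0115800 (4915 against 1) was 5146-fold higher, interval 923 to 203300, and Os11g0306400 was lower, at -6.44 ± 0.74. The count was 99 in the fit on 6 libraries (91 shared). It was 265 without IR64 replicate 1, 356 without IR64 replicate 2, 308 without OsEPF1-oeS replicate 2 and 297 without OsEPF1-oeS replicate 3. It was 972, the highest, without OsEPF1-oeS replicate 1, which stood apart from its group in the principal components. On the IR64 course that library lay at 4.93, beside the IR64 libraries at 4.92 to 5.07. OsEPF1-oeS replicates 2 and 3 lay earlier, at 4.70 and 4.59. Without replicate 1, CYP704B2 was at -3.97, CYP703A3 at -3.95, DPW at -7.98 and PKS1 at -5.39. These larger changes rest on the 2 libraries placed earlier. Calls of OsSLAC1, PRK, PAIR2, ZEP1, DPW, PKS1, PKS2 and ABA8OX2 were lost in 8 cases without IR64 replicate 1 (adjusted p 0.055 to 0.19), 5 without IR64 replicate 2 (0.063 to 0.13) and 2 without IR64 replicate 3 (0.069 to 0.096). Losses numbered 1 without OsEPF1-oeS replicate 1 (0.068), 5 without OsEPF1-oeS replicate 2 (0.063 to 0.22) and 6 without OsEPF1-oeS replicate 3 (0.076 to 0.37). The 6-library fit lost all of these and CYP704B2, CYP703A3, RBCS4 and PSBS1. DESeq2 did not call PKS1 or PKS2, and PKS1 was not called without a filter on low counts. ABA8OX2 was also lost without both OsEPF1-oeS replicate 1 and IR64 stage 3 replicate 1.

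In mature florets, 541 genes differed, 206 higher and 335 lower, a higher share of 38.1% that was 31.7% with RLE and 51.8% with upper-quartile scaling. Of the 10 circadian clock genes, the pseudo-response regulator genes PRR37 (Os07g0695100) and PRR73 (Os03g0284100) were higher by 1.38 ± 0.26 (adjusted p = 0.0028) and 0.99 ± 0.23 (adjusted p = 0.016). The list ranked high (median 0.34, 0.0144; adjusted p = 0.465 with an estimated correlation; 2 higher adjusted over the list alone). A difference in harvest time between the lines was not tested as a source of these clock values. OsICE1 (Os11g0523700) and OsICE2 (Os01g0928000), bHLH factors of the stomatal list, were lower, at -0.60 ± 0.13 and -0.65 ± 0.12. BRD1 (Os03g0602300), of brassinosteroid synthesis, was lower, at -0.72 ± 0.16 and SWEET11 at -0.68 ± 0.14. Of the photosynthesis, tapetum, meiosis, meristem, late pollen and heat shock lists edgeR called 0 genes, with 2, 1, 1, 1, 0 and 1 at an unadjusted p under 0.05, and DESeq2 called 1 tapetum and 1 meristem gene. The photosynthesis list had a median of -0.15 (0.398), and the secondary wall list ranked low with 0 called by edgeR, 6 at an unadjusted p under 0.05 and 2 called by DESeq2 (median -0.52, 0.0115; adjusted p = 0.625 with an estimated correlation). The lines lay -0.02 apart on the developmental course. By ID, Os06g0265100 (394 against 0) was at least 98.1-fold higher and Os02g0137700 lower, at -3.75 ± 0.44. The fit on the 6 mature libraries called only 8 genes, 6 of them shared, and lost every named call of a list gene here except OsEPF1, and that of Os02g0137700. DESeq2 called 977 genes but not Os08g0187900, and the count was 274 without IR64 replicate 2 and 287 without OsEPF1-oeS replicate 2. OsICE1, OsICE2, PRR73, BRD1, SWEET11 and the ID Os08g0187900 (-3.43 ± 0.62) lost 2 calls without IR64 replicate 1 (adjusted p 0.056 to 0.093), and 5 without IR64 replicate 2 (0.053 to 0.14). They lost 1 without OsEPF1-oeS replicate 1 (0.063), 6 without OsEPF1-oeS replicate 2 (0.051 to 0.11) and 1 without OsEPF1-oeS replicate 3 (0.055).

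Averaged over the 6 stages, 2830 genes differed, 1210 higher and 1620 lower, of which 162 and 252 by at least 2-fold. Of the 31 photosynthesis genes, 25 were lower and 1 higher (28 and 1 adjusted over the list alone; median -0.53, 5.3e-22; adjusted p = 0.234 with an estimated correlation). The chlorophyll-binding protein gene CAB2R (Os01g0600900) was lower, at -1.06 ± 0.17 (adjusted p = 9.5e-05), PSBS1 at -0.93 ± 0.10, SBP at -1.16 ± 0.19 and the Rubisco activase gene RCA (Os11g0707000) at -0.52 ± 0.07. CAB1R (Os09g0346500), of the same family as CAB2R, was higher by 0.78 ± 0.15 (adjusted p = 9.9e-04). Of the tapetum genes 6 were lower, among them TDR at -0.64 ± 0.10, TIP2 (Os01g0293100) at -0.33 ± 0.07, CYP704B2 at -0.98 ± 0.22 and RAFTIN1 at -1.18 ± 0.22. The list ranked low (median -0.34, 8.9e-07; adjusted p = 0.145 with an estimated correlation; 7 lower adjusted over the list alone). EAT1 was lower, at -1.22 ± 0.30, with a call lost without IR64 stage 1 replicate 2 (adjusted p = 0.089). In the secondary wall list PAL4 (Os02g0627100) was lower, at -1.25 ± 0.28 and PAL6 (Os04g0518400) at -2.01 ± 0.39, both of phenylpropanoid synthesis. The list ranked low (median -0.40, 7.6e-05; adjusted p = 0.323 with an estimated correlation; 3 lower, 4 adjusted over the list alone). In the cuticle list 5 genes were lower (0.00940; adjusted p = 0.109 with an estimated correlation; 5 adjusted over the list alone), with Lsi6 at -1.53 ± 0.11 (adjusted p = 1.5e-11), GL1-1 at -0.66 ± 0.12 and the wax regulator gene WR1 (Os02g0202000) at -0.67 ± 0.18.

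Of the 12 sugar transport and invertase genes, SUT1 was higher in the mean by 0.71 ± 0.11 (adjusted p = 2.7e-05). CIN2 was lower, at -0.60 ± 0.06 (adjusted p = 9.8e-09) and SWEET11 at -0.53 ± 0.06 (adjusted p = 2.0e-07), with the list not called (0.282). Of the 20 abscisic acid and dehydration genes 3 were lower, the synthesis gene NCED3 (Os03g0645900) at -1.05 ± 0.24 and the breakdown genes ABA8OX1 (Os02g0703600) at -0.65 ± 0.17 and ABA8OX2 at -0.49 ± 0.08 (list 0.276). In the guard cell function list of 12 genes PHOT1a was higher by 1.21 ± 0.22 and the potassium channel gene OsKAT3 (Os02g0245800) lower, at -0.40 ± 0.11 (list 0.668). In the stomatal list OsMUTE (adjusted p = 1.2e-06) and OsFAMA (adjusted p = 1.7e-09) were called lower, without a mean fold because OsEPF1-oeS held 0 counts at some stages, and OsICE1 was lower, at -0.24 ± 0.04. OsEPFL9a (Os01g0914400), which encodes a peptide that promotes stomatal formation, was higher by 0.29 ± 0.07 (adjusted p = 0.0097). In the floral organ list of 19 genes 3 were higher and 3 lower, 4 and 7 adjusted over the list alone (0.462). OsMADS17 (Os04g0580700) stood at 0.21 ± 0.05 and OsMADS16 (Os06g0712700) at -0.18 ± 0.04. Lists not called in the mean were gibberellin and brassinosteroid (0.569; 2 of 12 lower), heat shock (0.833; HSP17.9A lower, at -1.01 ± 0.16), late pollen (0.948; 0 called by edgeR and DESeq2, 0 at an unadjusted p under 0.05), meristem (0.920; the cytokinin activation gene LOG, Os01g0588900, lower, at -0.18 ± 0.05) and meiosis (0.947; MEL1, Os03g0800200, an Argonaute gene of germ cells, higher). The clock list (0.567; 0 called by edgeR and DESeq2, 0 at an unadjusted p under 0.05) and the cell cycle list (0.668; 0 called by both, 1 at an unadjusted p under 0.05) were not called either. By ID, Os03g0115800 and Os06g0265100 were called higher and Os11g0306400 and Os06g0347300 lower, without a mean fold because groups of 3 or fewer counts enter it. With the mature libraries left out, 4282 genes were called. Calls that depended on single libraries were those of MEL1 and CYP703A3, each lost in 26 of the 36 fits without 1 library (adjusted p 0.051 to 0.10 and 0.052 to 0.11), and of the receptor gene OsER2 (Os02g0777400) in 30 (0.051 to 0.12). BRD1 and OsMADS5 (Os06g0162800) lost theirs in 19, GL1-4 (Os02g0621300) and OsMADS14 (Os03g0752800) in 18 and CESA4 (Os01g0750300) in 13. Without a filter on low counts the calls of MEL1, CYP703A3, OsER2 and OsMADS14 were lost. Those of CYP703A3, CESA4, GL1-4 and OsMADS14 were lost with upper-quartile scaling and those of OsER2 and OsMADS5 with RLE. OsER2 was also lost at the filter of 5 CPM, BRD1 with developing stages alone, and MEL1 without IR64 stage 3 replicate 1 and OsEPF1-oeS stage 5 replicate 1, which stood apart from their groups.

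**Figure D3:**
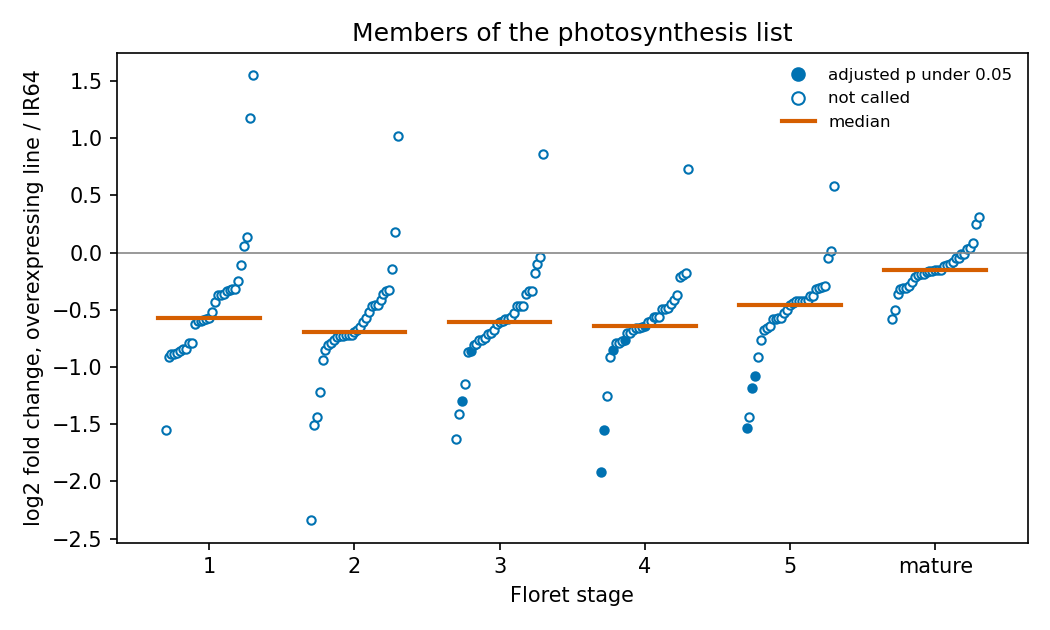
Log2 fold change of each of the 31 photosynthesis genes, OsEPF1-oeS minus IR64, at each stage (points, genes, filled where the adjusted p was under 0.05; bar, list median; n = 3 per line and stage). The median was -0.57, -0.69, -0.61, -0.64 and -0.46 at stages 1 to 5 and -0.15 in mature florets.

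Genes called in the same direction in 2 or more stages numbered 404, 203 higher and 201 lower, out of 747 higher and 1227 lower in at least 1 stage. Of these, 15 were higher and 3 lower in all 6, and 67 were called in opposite directions in different stages. No IR64 library is shared between stages. The stages do share 1 fit with a common spread per gene, which by itself favours calls of the same genes. The values for independent lists are therefore a low yardstick and not a test. Stages 1 and 2 shared 86 higher genes, against 0.594 for independent lists, and 51 lower ones, against 0.675. Stages 4 and 5 shared 126 higher genes (3.29 for independent lists), stages 3 and 4 shared 89 lower genes (3.56), and stage 5 and mature florets shared 28 higher (2.34) and 21 lower (4.40). At an adjusted p under 0.01 the genes called in 2 or more stages numbered 208, and with DESeq2 calls 680.

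The position of each library on the IR64 course, on a scale in which the stage means lie at 1 to 6, gave lower mean values for OsEPF1-oeS at every stage. The difference was -0.06 at stage 1 (exact two-sided permutation p = 0.7), -0.22 at stage 2 (p = 0.1) and -0.18 at stage 3 (p = 0.1). It was -0.14 at stage 4 (p = 0.1), -0.26 at stage 5 (p = 0.2) and -0.02 in mature florets (p = 0.5), by exact permutation tests of 3 against 3, for which 0.1 is the smallest possible p. At stage 3 the lines stood at 2.82 ± 0.0787 and 3.00 ± 0.0715 (SD, n = 3). Over all tested genes the difference was -0.16 at both stage 1 and stage 5. On the course of the OsEPF1-oeS means, a version chosen after seeing the data, it ran from -0.35 at stage 5 to -0.03 in mature florets. The IR64 slope of each gene was the mean of the steps into and out of a stage, with 1 step at stages 1 and 5. It can cancel for a gene that peaks at the stage. At stage 5 the position averaged the steps from stage 4 and to mature florets, but the slope held the step from stage 4 alone. The stage 5 predictions are therefore uncertain in size. The SE of an observed change leaves out the error of the position itself. A change predicted from the position and this slope was set beside the mean change of 5 lists, with the position taken without their members. At stage 5 it was 0.293 for meiosis genes, against 0.318 ± 0.137 observed (SE, n = 3 per line), and 0.175 for cell cycle genes, against 0.163 ± 0.0875. At the same stage it was -0.652 for tapetum genes, against -1.86 ± 0.666, and -0.313 for secondary wall genes, against -0.848 ± 0.469. Over stages 1 to 5 it was 12.3% to 32.7% of the observed change for photosynthesis genes, 24.7% to 48.3% for tapetum genes and 20.5% to 37.0% for secondary wall genes. For cell cycle genes it had the opposite sign of the observed change at stage 2, 0.122 against -0.0153 ± 0.0830, and at stage 3, 0.138 against -0.0890 ± 0.0329. At stages 1 and 4 it was 0.0207 against 0.00270 ± 0.110 and 0.0991 against 0.0757 ± 0.0563. For meiosis genes it was -0.00281 against -0.119 ± 0.0660 at stage 1, -0.0216 against -0.198 ± 0.0689 at stage 2, 0.0181 against -0.287 ± 0.175 at stage 3 and 0.103 against 0.198 ± 0.167 at stage 4.

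**Figure D4:**
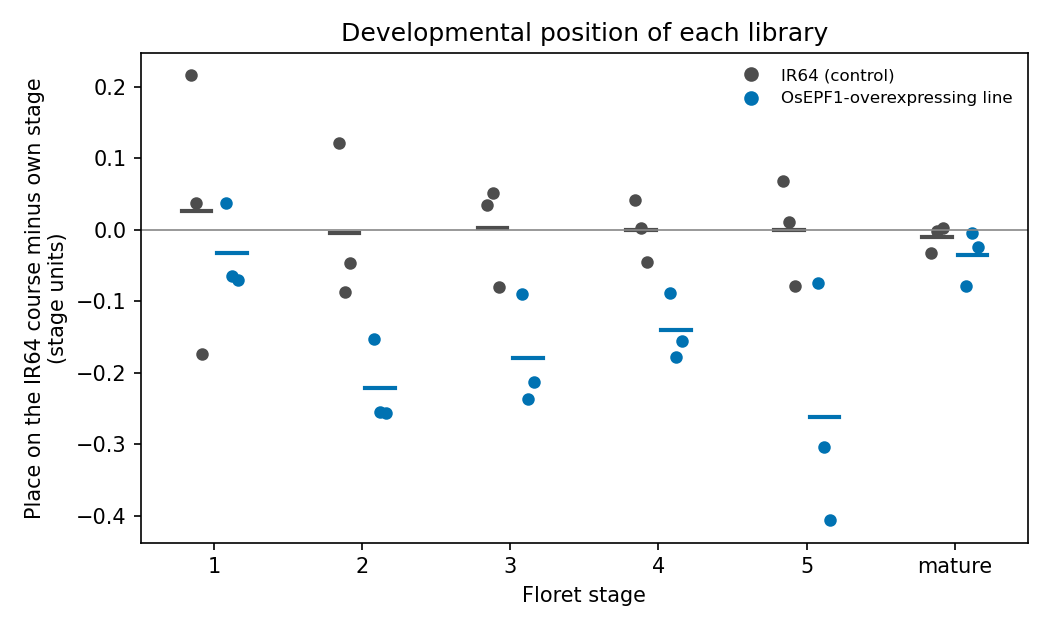
Position of each library on the IR64 course minus the number of its own stage, by stage and line (points, libraries; bars, group means; n = 3 per group). The group means differed by -0.26 to -0.02, and the smallest exact p was 0.1.

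In IR64, 2888 genes changed from stage 1 to stage 2, 2053 up and 835 down. Of the 31 photosynthesis genes 24 rose and 0 fell (median 1.21, camera adjusted p = 1.1e-19; adjusted p = 0.0856 with an estimated correlation), among them CAB2R at 2.72 ± 0.45, LHCB4 (Os07g0558400) at 1.53 ± 0.25 and PSBO (Os01g0501800), of the oxygen-evolving complex, at 1.30 ± 0.21. Of the tapetum genes 6 rose, EAT1 by 5.94 ± 0.68, UDT1 by 1.46 ± 0.22 and TDR by 1.38 ± 0.25 (0.00117; adjusted p = 0.176 with an estimated correlation). The recombinase gene DMC1A (Os12g0143800), 1 of 3 meiosis genes that rose, changed by 0.94 ± 0.18 (list 0.783). Of the 9 meristem genes 3 fell, the inflorescence regulator RFL (Os04g0598300) at -3.15 ± 0.35 and the homeobox gene OSH6 (Os01g0302500) at -0.79 ± 0.16 (0.00117; adjusted p = 0.102 with an estimated correlation). In the cell cycle list 2 genes fell, among them the topoisomerase gene TOP2 (Os02g0699700) at -0.51 ± 0.10 (0 and 10 adjusted over the list alone; 2.2e-06; adjusted p = 0.139 with an estimated correlation). Of the sugar genes 3 rose, SUT5 (Os02g0576600) by 2.21 ± 0.20 and SWEET11 by 1.10 ± 0.15 (1.1e-04; adjusted p = 0.00635 with an estimated correlation). Of the secondary wall genes 5 rose, with CAD2 (Os02g0187800), of lignin synthesis, at 2.14 ± 0.24 (2.3e-04; adjusted p = 0.208 with an estimated correlation). Of the cuticle genes 3 rose (0.0173; adjusted p = 0.0613 with an estimated correlation). Adjusted over the list alone, 28 photosynthesis, 6 tapetum, 6 sugar, 5 secondary wall and 4 cuticle genes rose and 5 meristem genes fell, while 3 meiosis genes rose and 1 fell. The count was 1620 without stage 1 replicate 3 and 1761 without stage 2 replicate 1.

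From stage 2 to stage 3, 5253 genes changed, 2959 up and 2294 down. All 17 cell cycle genes fell (median -0.80, 1.6e-11; adjusted p = 0.0383 with an estimated correlation), with the cyclin gene CYCB1;1 (Os01g0805600) at -0.87 ± 0.13 and the replication genes PCNA (Os02g0805200) at -0.75 ± 0.18 and MCM5 (Os02g0797400) at -0.84 ± 0.18. Of the stomatal genes 9 fell and 1 rose, OsTMM at -1.53 ± 0.25 (0.00247; adjusted p = 0.202 with an estimated correlation). Photosynthesis genes rose again, 18 of 31 with 0 falling (median 0.79, 3.9e-08; adjusted p = 0.301 with an estimated correlation), CAB2R by 1.79 ± 0.42. In the meiosis list 3 rose and 2 fell, PAIR2 rising by 2.28 ± 0.21, DMC1A by 1.17 ± 0.18 and ZEP1 by 1.11 ± 0.25 (0.412). Of the tapetum genes 9 rose and 1 fell (3.3e-04; adjusted p = 0.139 with an estimated correlation), CYP703A3 by 2.70 ± 0.51 and CYP704B2 by 2.12 ± 0.46. Sugar genes rose in 6 cases (6.9e-05; adjusted p = 0.00635 with an estimated correlation), SUT1 by 1.85 ± 0.28. Cuticle genes rose in 7 with 1 falling (5.7e-04; adjusted p = 0.0115 with an estimated correlation), the wax regulator WR2 (Os06g0604000) by 1.45 ± 0.12. RFL fell again, at -2.86 ± 0.42, with 3 meristem genes down and 1 up (0.00182; adjusted p = 0.123 with an estimated correlation), and 3 secondary wall genes rose (0.0212; adjusted p = 0.447 with an estimated correlation). Adjusted over the list alone, 27 photosynthesis, 10 tapetum, 7 cuticle, 6 sugar and 6 secondary wall genes rose, and 17 cell cycle, 9 stomatal and 8 meristem genes fell. In the tapetum and cuticle lists 1 gene each fell, in the stomatal and meristem lists 1 each rose, and of the meiosis genes 4 rose and 2 fell.

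From stage 3 to stage 4, 4074 genes changed, 1951 up and 2123 down, a rising share of 47.9% that was 56.8% with RLE scaling. Of the 24 stomatal genes 12 fell and 0 rose (median -0.45, 4.4e-06; adjusted p = 0.0599 with an estimated correlation), OsSPCH1 at -4.41 ± 0.68, OsMUTE at -2.93 ± 0.54 and OsTMM at -1.81 ± 0.27. Of the cell cycle genes 15 fell (median -0.81, 5.8e-12; adjusted p = 0.0359 with an estimated correlation), MCM5 at -1.30 ± 0.18 and PCNA at -1.11 ± 0.18. In the meiosis list 5 fell and 2 rose, PAIR1 falling, at -1.77 ± 0.29 and MEL1 at -2.07 ± 0.24 (0.04997; adjusted p = 0.361 with an estimated correlation). The tapetum list split, with 4 up and 4 down (0.340): UDT1 fell, at -2.10 ± 0.22 and EAT1 at -2.32 ± 0.42, while TDR rose by 1.65 ± 0.25 and PKS2 by 6.55 ± 0.69. Photosynthesis genes rose in 11 cases with 0 falling (median 0.58, 1.1e-07; adjusted p = 0.307 with an estimated correlation). Meristem genes fell in 5 (3.6e-04; adjusted p = 0.0754 with an estimated correlation), OSH6 at -1.18 ± 0.16. Floral organ genes fell in 7 (0.00182; adjusted p = 0.139 with an estimated correlation), OsMADS32 (Os01g0726400) at -0.87 ± 0.19. Of the heat shock genes 2 rose (0.0408; adjusted p = 0.340 with an estimated correlation). Adjusted over the list alone, 13 stomatal, 15 cell cycle, 10 floral organ, 6 meristem and 5 meiosis genes fell, while 1 stomatal, 2 meiosis, 2 heat shock and 13 photosynthesis genes rose. Of the tapetum genes 7 rose and 5 fell by that adjustment. OsEPF1 itself fell, at -1.21 ± 0.31, a call lost without stage 3 replicate 1 (adjusted p = 0.052) and in the fit on 6 libraries, which called 2628 genes.

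From stage 4 to stage 5, 2792 genes changed, 1639 up and 1153 down. Of the tapetum and pollen wall genes 10 rose and 2 fell (median 1.26, 4.3e-07; adjusted p = 0.0417 with an estimated correlation): DPW by 10.56 ± 1.24, the transporter gene ABCG15 (Os06g0607700) by 9.19 ± 1.30, the regulator PTC1 (Os09g0449000) by 8.01 ± 1.17 and CYP703A3 by 3.97 ± 0.49. Of the 11 meiosis genes 7 fell and 0 rose (median -1.20, 1.4e-12; adjusted p = 0.00635 with an estimated correlation), PAIR2 at -1.59 ± 0.21, ZEP1 at -1.99 ± 0.26 and CRC1 (Os04g0479000) at -1.59 ± 0.20. Of the cell cycle genes 13 fell (median -0.66, 1.4e-12; adjusted p = 0.0359 with an estimated correlation), the cytokinesis gene KN (Os03g0736500) at -1.11 ± 0.19. Of the stomatal genes 6 fell (7.9e-05; adjusted p = 0.102 with an estimated correlation), OsTMM at -2.49 ± 0.37, and of the photosynthesis genes 12 rose (median 0.61, 7.5e-09; adjusted p = 0.266 with an estimated correlation). Of the secondary wall genes 5 rose (4.5e-05; adjusted p = 0.171 with an estimated correlation). Adjusted over the list alone, 12 tapetum, 21 photosynthesis and 10 secondary wall genes rose, and 9 meiosis, 15 cell cycle, 8 stomatal and 2 tapetum genes fell. By ID, Os07g0599300 had 11248 counts against 0 and was at least 4261-fold higher. The count was 1853 without stage 4 replicate 2 and 1756 without stage 5 replicate 1.

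From stage 5 to mature florets, 18341 genes changed, 68.6% of those tested, 9636 up and 8705 down, a rising share of 52.5% that was 45.2% with upper-quartile scaling. All 9 late pollen genes rose (3.9e-08; adjusted p = 0.0132 with an estimated correlation; fitted median 14.70, or 11.58 with genes at 0 set to their bound). The profilin gene PRF1 (Os10g0323600) had 80196 counts against 0, at least 36660-fold higher, and the beta-expansin gene EXPB9 (Os10g0548600) 369977 against 0, at least 169100-fold. The near-identical expansin genes EXPB10 (Os03g0106800) and EXPB1a (Os03g0106500) had 78487 against 0 and 26605 against 1, values that the counting could have shared between copies. Of the photosynthesis genes 30 rose and 0 fell (median 2.56, 1.1e-09; adjusted p = 0.233 with an estimated correlation), PSBS1 by 6.59 ± 0.25 and RCA by 5.96 ± 0.21. Of the tapetum genes 13 fell and 2 rose (median -2.09, 0.00157; adjusted p = 0.191 with an estimated correlation), PKS1 having 2 counts against 72542 (26450-fold lower, interval 7321 to 218400). Of the stomatal genes 18 fell and 0 rose (median -1.92, 2.1e-07; adjusted p = 0.0359 with an estimated correlation), OsICE1 at -4.14 ± 0.11 and OsSPCH2 (Os02g0257500) with 0 counts against 132. The guard cell potassium channel gene OsGORK (Os06g0250600) rose by 5.75 ± 0.43, 1 of 7 guard cell function genes that rose with 1 falling. Of the 19 floral organ genes 14 rose and 3 fell (0.00287; adjusted p = 0.155 with an estimated correlation), OsMADS13 (Os12g0207000), of ovule identity, by 4.10 ± 0.20. Of the secondary wall genes 11 rose and 1 fell (0.00224; adjusted p = 0.307 with an estimated correlation), the cellulose synthase gene CESA4 by 3.97 ± 0.27.

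In the same step 15 cell cycle genes fell (median -0.94, 0.00145; adjusted p = 0.307 with an estimated correlation), and 9 of 11 heat shock genes rose (0.0650). In addition 12 abscisic acid and dehydration genes rose and 5 fell, with the dehydrin gene RAB16A (Os11g0454300) at 4.95 ± 1.07, and 6 gibberellin and brassinosteroid genes rose and 6 fell. Of the clock genes 2 rose and 5 fell, LHY (Os08g0157600) at 2.04 ± 0.45 and FKF1 (Os11g0547000) at -3.67 ± 0.49. Over the 4 earlier steps edgeR and DESeq2 called 0 clock genes, with 0 at an unadjusted p under 0.05. Harvest time was not tested as a source of the changes in the step to mature florets. With upper-quartile scaling the median log2 change of all genes was -0.15, against 0.02 with TMM, and the list changes of this step are relative to that shift. Adjusted over the list alone, the list counts of this step were the ones given, apart from 31 photosynthesis genes up and 1 heat shock gene down.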

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

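The tests of developmental position and library size and the counts of other splits given here were chosen only after the results were seen.

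The genotype difference itself differed between stages for 599 genes in the interaction test. Among them were the following genes of the lists. OsEPF1 had an interaction adjusted p of 3.3e-09, with a log2 change of 9.15 at stage 1 and 12.69 at stage 5. Lsi6 (9.8e-06) was called lower at stages 3, 4 and 5, lowest at stage 4 with -3.29 ± 0.28. EAT1 (0.0017) was called at stage 2 alone, at -4.41 ± 0.58. PAIR2 (0.0032) was lower at stage 3 at -0.92 ± 0.20 and higher at stage 5 by 0.91 ± 0.20, and ZEP1 (0.016) at -1.16 ± 0.25 and 0.94 ± 0.25. In IR64 both genes rose from stage 2 to stage 3 and fell from stage 4 to stage 5. An earlier place of the line on that course would give the same signs, which was not tested for single genes. HSP17.9A (0.0034) was called lower at stage 5, OsICE2 (0.01) lower and PRR37 (0.012) and PRR73 (0.044) higher in mature florets, and GA3ox1 (0.038) higher at stage 4. In IR64, EAT1 rose from stage 1 to stage 2 and GA3ox1 fell from 247 counts at stage 3 to 1 at stage 4. For these 2 genes too an earlier place would give the signs seen, which was not tested.

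In all 6 single-stage genotype comparisons and the 5 steps, 3 against 3 libraries give 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many calls. The real count and the highest of the other splits were 223 and 11 at stage 1, 315 and 1 at stage 2, 453 and 0 at stage 3, 635 and 1 at stage 4, 654 and 386 at stage 5, and 541 and 393 in mature florets. For the steps they were 2888 and 0, 5253 and 1, 4074 and 0, 2792 and 1, and 18341 and 76. The median of the other splits was 121 calls in mature florets and 0 at stage 5. The 386 calls at stage 5 came from joining OsEPF1-oeS replicate 1 with IR64 replicates 1 and 2. For the mean of 6 stages and the interaction, 50 labellings were compared with the real one included. Again 1 gave as many calls, with 2830 against 2 and 599 against 21 at most. The labels were redrawn within each stage, as if libraries of different stages were independent. The replicate numbers paired IR64 libraries of stages 3 and 4 and of stages 4 and 5, so these labellings do not exclude chance.

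As a set, OsEPF2, OsMUTE and OsFAMA had a lower mean in OsEPF1-oeS over stages 1 to 4, with each called at each of these stages except OsFAMA at stage 1. A later or earlier place of the line on the IR64 course predicted a mean log2 change of 0.02, against the observed -3.51, and left -3.53 ± 0.12 (SE). Rises and falls of these genes in IR64 can cancel in that prediction, and the SE leaves out the error of the position. At each of stages 1 to 4, IR64 held at least 170 counts of OsEPF2, 28 of OsMUTE and 20 of OsFAMA. OsEPF1-oeS held at most 65, 5 and 6, which argues against a place elsewhere within these stages as the cause. The OsEPF1-oeS libraries of these stages held fewer reads, with a lowest ratio of 0.696 at stage 3, but the highest ratio of raw counts over the 3 genes was 0.0250 at that stage, far below it. The overexpression of OsEPF1, which defines the line, stays open as an explanation that no test here bears on.

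The photosynthesis list was lower in OsEPF1-oeS at stages 1 to 5. Position predicted -0.12 of the observed mean of -0.57, or 21.9% of it, and left -0.45 ± 0.09 (SE). The SE leaves out the error of the position, and at stage 5 the slope held only 1 of the steps averaged in the position. Whether position is the whole cause is therefore not decided. The source of the change stays open, with no other explanation tested, and no genotype call of this list held with an estimated correlation.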

How the results depend on the processing

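The stomatal list without OsEPF1, the block over stages for the list tests of the IR64 steps, the 2 further versions of the position and the fits without 2 libraries that stood apart were tests chosen only after the results were seen. No direction reversed: over 265 gene and comparison pairs drawn from the lists and the naming rule, 190 kept their call throughout, and of 5720 values 5296 kept it and 424 lost it, 340 of these with 1 library left out and 44 of 188 in the fits on 6 libraries. The pairs were ones called in these data, which made a reversal unlikely beforehand. Of the values, 3630 came from fits with 1 library left out, which share nearly all their libraries and raise the share kept. With DESeq2, counts moved by more than 1.5 times at stage 1 (381), stage 2 (540), stage 3 (704) and stage 4 (1088). They also did so in mature florets (977) and for the interaction (1501). In the fit on 6 libraries they did so at stage 1 (144), stage 3 (56), stage 4 (396) and stage 5 (99). The same held there for mature florets (8) and the step to stage 4 (2628). The cause was not tested. The 6-library fits have fewer samples and take the spread from the 2 groups alone, and these were not told apart. With developing stages alone the mean called 4282 and the interaction 388 genes. Without IR64 stage 3 replicate 1 and OsEPF1-oeS stage 5 replicate 1, stage 5 called 1076 and the interaction 904. Genes shared by 2 or more stages numbered 208 at an adjusted p under 0.01 and 680 with DESeq2. With the correlation estimated per list, 0 genotype and 10 development list calls held.

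With 1 library left out, the counts ran from 119 to 203 at stage 1, 159 to 239 at stage 2, 213 to 449 at stage 3, 286 to 795 at stage 4, 265 to 972 at stage 5, 274 to 792 in mature florets, 1620 to 2322 for the step to stage 2 and 1756 to 2533 for the step to stage 5. The other counts stayed within 1.5 times.

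The replicate number as a block gave 160, 304, 414, 529, 574 and 391 calls at the 6 stages, 2465 in the mean and 501 in the interaction, and 3165, 5450, 4334, 2954 and 18399 in the 5 steps. For the genotype comparisons the numbers did not pair the libraries by the correlation of their deviations (lowest -0.117, -0.117, -0.280, -0.129, 0.0716 and -0.0977), nor in the steps to stage 2 (0.0361), stage 3 (0.0945) and maturity (-0.286); each library correlated best with its own number in stage 5 of the genotype comparisons and in the steps to stages 2, 4 and 5. The block ended 12 named calls (PHOT1a at stage 1, OsFAMA at stage 2, PAIR3 at stage 3, GA3ox1, OsMUTE and REC8 at stage 4, ABA8OX2 and ZEP1 at stage 5, Os08g0187900 in mature florets, and MEL1, OsER2 and OsMADS14 in the mean) and no named call in the steps to stages 4 and 5, where the numbers pair the libraries. Depth limits what can be said of OsMUTE and OsFAMA in OsEPF1-oeS, which had at most 6 counts per group.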

Other observations

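The tests on neighbouring genes given here were chosen only after the result was seen.

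Genes that differed between the lines tended to lie beside one another. Of the 413 genes that differed at least 2-fold in the mean of 6 stages, OsEPF1 left out, 57 pairs lay within 3 tested genes of each other and 50 of them had the same direction. Random sets of like expression gave 19.7 pairs on average and 38 at most in 10000 draws (permutation p = 1.0e-04, the smallest the draws can give), and sets from genes changed in the 4 IR64 steps between developing stages 50 at most (permutation p = 1.0e-04). These values argue against chance placement. They do not settle the co-regulation of neighbours. The sets from the 4 steps were random parts of 1175 to 1907 genes, which separates neighbours, and were not matched for expression. The step to maturity was left out of the test. Chromosome segments that differ between the lines may be a source and stay open: 31 of 97 genes in a pair and 89 of 316 others were called in 3 or more single stages (Fisher exact two-sided p = 0.52), a test that decides neither way. One run, singled out after its values were seen, holds 5 of 5 tested genes from Os04g0635100 to Os04g0635650 higher by 1.47 to 2.66, while the 14 tested genes between it and OsEPF1 had a median of -0.00 (-0.31 to 0.10).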
